A study of Mus musculus with 10 samples.

How the data were processed

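RNA was extracted from mouse skin with trizol and made into libraries with an Illumina stranded mRNA kit from 250 ng of total RNA, per the labels' protocols. There was 1 library per mouse, and the series' design text describes 5 WT and 5 KI mice. Genotype was taken from the titles. Replicate numbers were given in accession order and pair nothing. The submitters' processing notes name FastQC, STAR 2.5.2b, Picard 2.8.1, featureCounts, DESeq2 1.14.1 and the build GRCm38, with no role or order. Each deposited table has the columns of an RSEM gene table. Expected counts, TPM, FPKM and lengths in it were made by the authors, per the file headers, and the RSEM version, the annotation release and the strand setting are not given in the sources used here.

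The deposited expected counts are estimates that need not be whole (10.4% to 12.2% of values per library were fractional) and were rounded to whole numbers before testing. TPM values deposited by the authors were used only to check that each library sums to the same total, FPKM values deposited by the authors were not used, and the deposited effective lengths entered an alternative only. Gene identifiers were named from GENCODE M21, which matched 55141 of 55487 identifiers, and the 346 others held 0.0507% of counts. Coordinates are those of that annotation on GRCm38.

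Depth ranged from 18.96 to 26.43 M expected counts per library. Mitochondrial genes held 3.58% to 5.31% of counts. No pair of libraries agreed within sampling noise, since the lowest chi-square per gene was 29.7. Intervals on ratios of counts are exact binomial at 95% and cover counting error only.

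Genes were kept by edgeR's filterByExpr with its defaults (minimum count 10, minimum total 15), which left 17321 genes and removed 0.127% of counts. KI was compared with WT by the quasi-likelihood test of edgeR 4.0.16 (robust fit, TMM normalization, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use TMM library sizes. The KI effect within each title prefix and the difference of both effects came from a model with an interaction. Hamp was also tested by an exact two-sided permutation test of log2 CPM over all assignments of 5 against 5 libraries. Intervals on differences of list levels come from linear models of the 10 library levels, or of those named.

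The design, the alternatives, the rule for named genes and 29 gene lists were fixed before the data were examined. Of 550 list names 3 were not matched. Lists with at least 3 measured members (28 lists) were tested by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over lists, and beside it by camera with an estimated correlation, which called no list, and by fry, which called 8 lists higher and 8 lower. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. At an unadjusted p under 0.05 camera with an estimated correlation gave 4 lists. A list level is the mean log2 CPM of its measured members. The lists cover iron handling, heme synthesis, BMP targets, cell cycle, activated, cornified and basal keratinocytes, neutrophil and interleukin 17 axis cytokines, neutrophils, macrophages and dendritic cells, T and NK cells, B and plasma cells, mast cells, interferon response, hair shaft, sebaceous gland, adipocytes, skeletal and smooth muscle, fibroblasts, endothelium, melanocytes, Schwann cells, red blood cells, hypoxia and glycolysis, NRF2 targets, oxidative phosphorylation, immediate early genes and sex-linked genes.

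Named genes were Hamp and Hamp2, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 CPM, Tfrc, Slc40a1, Fth1 and Ftl1, and up to 4 members of each list with the smallest p. A gene named outside this rule is said to be so.

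Alternatives were other normalizations (DESeq2 size factors, upper quartile), no filter or a stricter filter (minimum count 50), offsets from effective lengths, a non-robust fit, the title prefix as a block, levels of the muscle or hair list as a covariate, 1 surrogate variable (sva 3.50.0), each title prefix alone, each library left out in turn, DESeq2 1.42.0 and limma-voom. A covariate of Y-linked expression was not run, because Y-linked genes held at most 2 counts in any library. Leaving out WT 2 and KI 2 together, the title prefix with the muscle level, and the adipocyte level as a covariate were added after the data were seen.

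The tests were tried on simulated counts with the real means, library sizes and 17321 genes. For KI against WT the test recovered 25.4% of 67 genes changed 1.5-fold, 70.2% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, with 6 false calls (4.35% of calls). The changed genes were drawn from genes outside the lists with a mean of at least 50 counts. The recovered shares, also those for the interaction, thus do not hold for genes with fewer counts. Far fewer genes were changed than the 30.9% called in the real libraries, which also affects the adjusted p. With no change simulated 1 gene and 0 lists were called. Genes were simulated independently of each other, so the 0 lists do not show how often the preset correlation gives false calls for correlated members. In the real libraries the estimated correlation within lists ran from -0.00877 for iron handling to 0.84 for skeletal muscle. For the interaction the recovered shares were 0%, 4.48% and 54.5%. Shared 50-base windows of Hamp and Hamp2 transcripts were counted with Biostrings 2.70.1, and figures were drawn with matplotlib 3.10.9.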

Results

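Skin from 10 mice was profiled by RNA sequencing, 5 wild type mice (WT) and 5 mice of a genotype written in the labels as Hamp1-KI ker (KI in what follows). Hamp encodes hepcidin, the peptide hormone that lowers iron export by acting on ferroportin, and the series concerns skin in which hepcidin is overexpressed. The labels do not spell out "ker". Each library held between 18.96 and 26.43 M expected counts over 55487 genes. Animal titles carry the prefix EAS37 (3 WT, 2 KI) or EAS42 (2 WT, 3 KI), whose meaning the labels do not give. The comparison asked which skin genes differ between the genotypes.

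**Figure D1:**
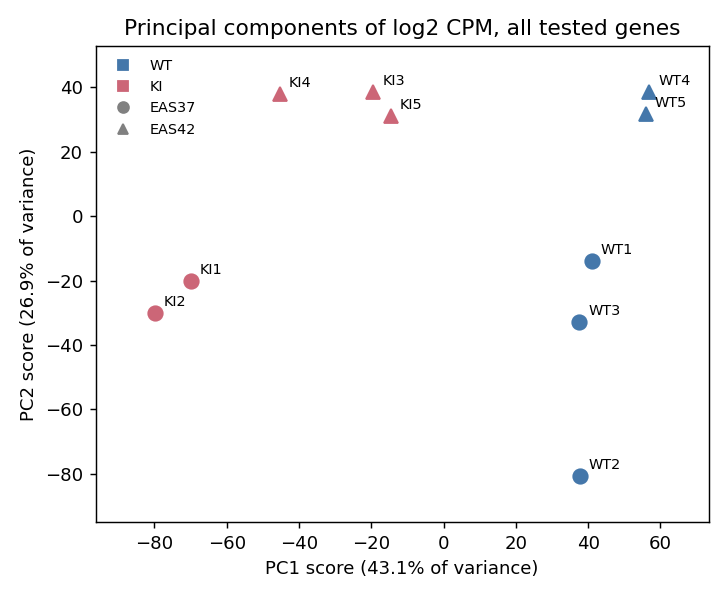
Principal component scores of the 10 libraries from log2 CPM of all tested genes, with colour for genotype and shape for title prefix. All 5 KI libraries have PC1 scores below 0 and all 5 WT libraries above 0 (43.1% of variance), and the title prefixes part along PC2 (26.9%), at -80.7 to -14.1 for EAS37 and 31.1 to 38.5 for EAS42.

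Hamp was 44.3 times as abundant in KI skin as in WT skin. It stood at 2.46 ± 0.615 CPM in WT and 109 ± 34.3 CPM in KI (SD, n = 5 each), and every KI library exceeded every WT library. The log2 fold change was 5.47 ± 0.26 (SE; edgeR adjusted p = 3.78e-06), and an exact two-sided permutation test gave p = 0.00794, the smallest that 5 against 5 libraries allow. The log2 fold change was 5.62 with EAS37 and 5.46 with EAS42. Hamp (ENSMUSG00000050440) lies on chromosome 7 of GRCm38, from 30942368 to 30944032 on the minus strand. Its neighbouring paralog Hamp2 (ENSMUSG00000056978, chromosome 7, 30922372 to 30924681) went the other way, from 46.8 ± 22.3 CPM in WT to 3.18 ± 5.26 CPM in KI, a log2 fold change of -3.89 ± 1.05 (SE; edgeR adjusted p = 0.023). KI libraries held between 0 and 12.5 CPM of Hamp2 and WT libraries between 25.9 and 83.0 CPM. The Hamp2 call was lost with the muscle level in the model (-2.51, adjusted p = 0.42), with no filter (adjusted p = 0.0511), with prefix EAS42 alone (-2.70, adjusted p = 0.213), without KI 1 (adjusted p = 0.0581) and without KI 4 (adjusted p = 0.0547). Hamp and Hamp2 share part of their sequence, so their split of reads carries some uncertainty.

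**Figure D2:**
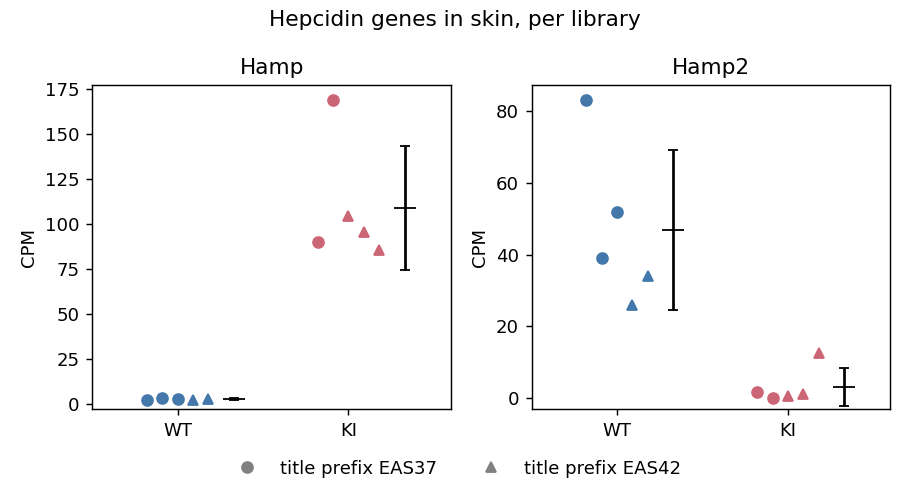
CPM of Hamp and Hamp2 in each library, with circles for EAS37 and triangles for EAS42, and the group mean with its SD in black (n = 5). Hamp lies between 85.6 and 169 CPM in KI libraries and between 1.86 and 3.33 CPM in WT libraries, while Hamp2 is at most 12.5 CPM in KI libraries.

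KI skin differed from WT skin in 5351 of 17321 tested genes (30.9%; edgeR adjusted p under 0.05), 2699 higher and 2652 lower, and 1617 of them by at least 2-fold. Among the 10 largest rises were keratin 6b, a keratin of wounded and hyperproliferative epidermis (Krt6b, 2.23 ± 3.30 to 418 ± 338 CPM) and the cornified envelope precursor Sprr1b (0.794 ± 0.610 to 93.8 ± 59.7 CPM). Others were the acute phase apolipoprotein Saa3 (0.0869 ± 0.0728 to 41.1 ± 40.7 CPM) and the stefin genes BC100530 (2.56 ± 1.38 to 533 ± 227 CPM) and Stfa3 (1.84 ± 0.303 to 207 ± 64.0 CPM), which encode inhibitors of cysteine proteases (mean ± SD, n = 5 each). The remaining 5 were Igfl3, Gm6093, 2610528A11Rik, Cdhr1 and Olah. WT totals of some were small, at 10 counts for Saa3, 11 for Igfl3 and 2 for Olah. For Olah the ratio of totals was 169.7 (95% interval 46.6 to 1408, counting error only). Among the 10 largest falls were the cardiac type actin Actc1 (43.3 ± 47.1 to 2.28 ± 3.29 CPM) and the carnosine synthase Carns1 (126 ± 29.5 to 15.0 ± 9.44 CPM). So were the anion exchanger Slc26a7 (7.30 ± 7.51 to 0.648 ± 0.603 CPM) and the peripheral myelin protein Pmp2 (5.32 ± 4.03 to 0.702 ± 0.368 CPM). The remaining falls were Hamp2, A930003A15Rik, Tnfrsf13c, Gpha2, Chrna4 and Sbk3. Stefin genes are near-identical copies, Igfl3 overlaps Gm44613 and Carns1 overlaps Gm17552 and AC109138.8, so the values of these genes are uncertain.

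The fall of Actc1 (edgeR adjusted p = 0.0322) kept its sign, but the call was lost, with log2 fold changes between -4.48 and -1.87, with the muscle level in the model (adjusted p = 0.535), under limma-voom (0.0781), with no filter (0.0688), or without KI 1 (0.0739), KI 2 (0.0685), KI 4 (0.0723), KI 5 (0.0612), WT 4 (0.0634) or WT 5 (0.0617). The Actc1 groups overlapped, with 8.02 CPM in KI 3 against 6.58 CPM in WT 3 and 7.36 CPM in WT 2. Its highest WT values were 102.52 CPM in WT 4 and 86.35 CPM in WT 5. Slc26a7, whose groups overlapped as well, lost its call with no filter (0.0756), under limma-voom (0.0698), and without KI 1 (0.0509), KI 2 (0.0562), KI 4 (0.0513), WT 4 (0.0579) or WT 5 (0.0591), with log2 fold changes between -3.67 and -2.96. With the muscle level in the model, A930003A15Rik and Carns1 alone of the 10 largest falls passed. Saa3 lost its call under limma-voom (0.0602). Groups did not overlap for 3524 genes (20.3% of those tested, against 0.794% by chance). With EAS42 alone 2488 genes passed, against 5064 with EAS37 alone. With the skeletal muscle level of each library in the model the number fell to 414, while all 5351 genes kept their sign, their median absolute log2 fold change went from 0.69 to 0.46 and their median SE from 0.157 to 0.196.

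Keratinocyte genes of activated and wounded epidermis rose strongly. Of 28 measured members of that list, of 45 matched, 24 rose and none fell (25 rose adjusted over the list alone), with a median log2 fold change of 3.55 (also with Serpinb3a, which had 0 WT counts, at its lower bound). Members below the filter had higher total counts in KI, except Sprr3 (4 in WT and 2 in KI) and Serpinb3c (8 and 3). Sprr2a2 went from 8.02 ± 1.75 to 232 ± 146 CPM, Sprr2a3 from 0.388 ± 0.278 to 7.94 ± 3.60 CPM, and the interleukin 36 family cytokine Il1f8 from 2.84 ± 1.33 to 29.1 ± 7.85 CPM (SD, n = 5 each). Camera placed the list above other genes (adjusted p = 2.76e-16 with the preset correlation, adjusted p = 0.172 with an estimated correlation). Sprr2a genes share sequence and their split of reads is uncertain. With the muscle level in the model the median was 3.14 and 12 members passed. Cornified layer genes were mixed, with 18 higher, 3 lower and 20 not passing of 41 (19 higher and 4 lower adjusted over the list alone; camera adjusted p = 6.29e-07, and adjusted p = 0.447 with an estimated correlation). The late differentiation protease Casp14 rose from 59.7 ± 20.8 to 478 ± 86.2 CPM and filaggrin (Flg), which aggregates keratin filaments, from 60.9 ± 28.4 to 584 ± 141 CPM. The late envelope genes Lce1g and Lce1i, members of a gene family with similar copies, had log2 fold changes of 5.69 ± 0.29 and 2.70 ± 0.25 (SE). The cornified median was 1.1403 with EAS37 and 0.22 with EAS42. The list lost its call with EAS42 alone (adjusted p = 0.229) and with prefix and muscle level (adjusted p = 0.158).

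Basal keratinocyte genes moved both ways, with 3 higher and 3 lower of 12 (the same counts adjusted over the list alone). The basal keratin Krt14 rose from 3181 ± 1151 to 8489.9 ± 3048 CPM, whereas Krt15, a keratin of basal and hair follicle stem cells, fell from 4312 ± 787 to 1231 ± 725 CPM (adjusted p = 0.0564 with EAS42 alone). The list as a whole was not called (camera adjusted p = 0.909, downwards, with a median of -0.04, while fry pointed upwards).

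Cell cycle genes rose, 32 of 35 members and none lower (32 adjusted over the list alone), with a median log2 fold change of 1.139. Ccnb2, the cyclin B2 of mitotic entry, had a log2 fold change of 1.68 ± 0.20 (SE). The anaphase activator Cdc20 went from 9.46 ± 2.10 to 30.5 ± 10.1 CPM, the mitotic kinesin Kif20a from 7.82 ± 2.01 to 21.2 ± 4.37 CPM and the centromere histone Cenpa from 16.1 ± 1.49 to 40.4 ± 10.5 CPM (SD, n = 5 each). The camera adjusted p was 1.61e-13 with the preset correlation, and adjusted p = 0.358 with an estimated correlation. With the muscle level in the model the median was 0.83 and 4 members passed.

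Cytokine and chemokine genes of the neutrophil and interleukin 17 axis rose in all 7 measured members, of 20 written (7 adjusted over the list alone), with a median log2 fold change of 2.30. The chemokine Ccl20 went from 0.365 ± 0.268 to 6.42 ± 2.004 CPM, the interleukin 23 subunit Il23a from 0.189 ± 0.0890 to 1.32 ± 0.366 CPM and the NF-kappa-B cofactor Nfkbiz from 36.4 ± 3.40 to 69.7 ± 4.80 CPM (camera adjusted p = 1.03e-05, and adjusted p = 0.172 with an estimated correlation). Il17a and Il22 had 0 counts in both groups and were below the depth of these libraries. Other members below the filter went both ways. Total counts in WT and KI were 7 and 3 for Il17f, 8 and 4 for Il17c and 3 and 1 for Il12b. They were 0 and 204 for Cxcl5 and 11 and 104 for Cxcl2. Of 7 measured neutrophil markers, of 23 written, 4 rose and 1 fell (5 and 1 adjusted over the list alone), led by the gelatinase Mmp9 (5.88 ± 1.51 to 55.4 ± 14.8 CPM) and the chemokine receptor Cxcr2 (10 WT counts, 0.0848 ± 0.0835 to 3.60 ± 2.62 CPM). Members below the filter went both ways. Total counts went from 21 in WT to 7 in KI for Camp and were 3 in both for Elane. They went from 3 to 30 for Mmp8 and from 1 to 40 for Stfa2l1. The neutrophil list was called (camera adjusted p = 0.0112) with adjusted p = 0.352 under an estimated correlation. It lost its call under a stricter count filter (adjusted p = 0.553), and Ly6g had 0 counts in both groups.

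T and NK cell genes rose in 15 of 20 measured members (16 adjusted over the list alone), with a median log2 fold change of 1.15. The T cell receptor constant genes Trbc1 and Trbc2, similar copies of each other, went from 2.07 ± 0.420 to 8.03 ± 1.53 CPM and from 11.6 ± 3.02 to 28.0 ± 6.09 CPM, and the T cell surface receptor Cd5 from 1.19 ± 0.283 to 5.91 ± 1.56 CPM (camera adjusted p = 7.32e-09, and adjusted p = 0.172 with an estimated correlation). With the muscle level in the model the median was 1.16 and 4 members passed. Macrophage and dendritic cell genes rose in 8 of 20 members (8 adjusted over the list alone), among them the integrin Itgax (2.78 ± 0.746 to 7.69 ± 2.21 CPM), the Langerhans cell lectin Cd207 (8.42 ± 2.29 to 15.5 ± 3.97 CPM) and the class II gene H2-Aa (75.7 ± 15.2 to 127 ± 29.7 CPM). Camera gave adjusted p = 0.00155, and adjusted p = 0.447 with an estimated correlation, and the call was lost with prefix and muscle level in the model (adjusted p = 0.158). Oxidative stress genes of the NRF2 programme rose in 4 of 13 members (5 adjusted over the list alone; camera adjusted p = 0.00383, and adjusted p = 0.358 with an estimated correlation), led by the aldose reductase family member Akr1b8 (5.91 ± 1.34 to 21.1 ± 5.40 CPM). The NRF2 call was lost with the adipocyte level in the model (adjusted p = 0.370).

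**Figure D3:**
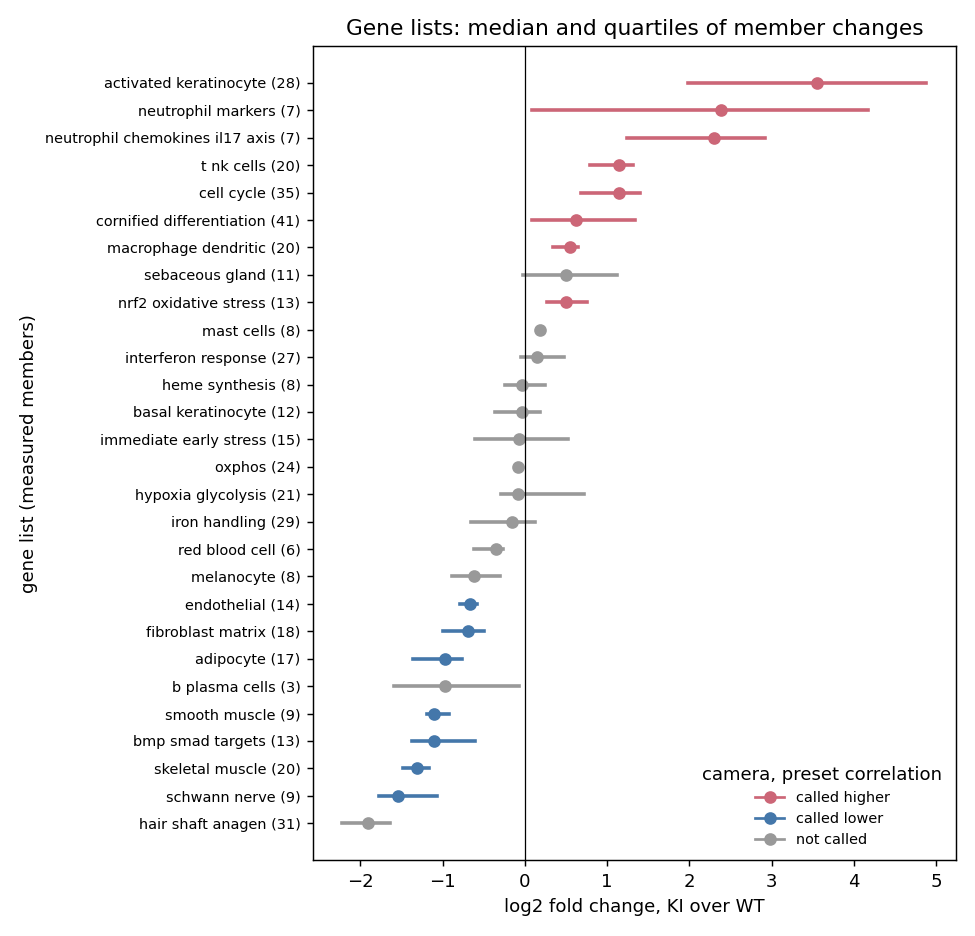
Median (point) and quartiles (line) of the log2 fold change, KI over WT, over the measured members of each of 28 gene lists, coloured by the camera call with the preset correlation. The activated keratinocyte list has the highest median (3.55), and the Schwann and nerve list has the lowest median among called lists (-1.55).

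Most marker genes of fat, vessels, nerve and smooth muscle fell, while fewer members of the matrix and skeletal muscle lists passed. Adipocyte genes fell in 11 of 17 members and none rose (14 adjusted over the list alone; median -0.97). The fatty acid binding protein Fabp4 went from 498 ± 67.2 to 263 ± 34.4 CPM and carbonic anhydrase 3 (Car3) from 1179 ± 228 to 388 ± 161 CPM. Endothelial genes fell in 12 of 14 members (13 adjusted over the list alone; median -0.67), and VE-cadherin, Cdh5, went from 49.4 ± 8.84 to 24.2 ± 3.50 CPM. Schwann and nerve genes fell in 8 of 9 members (8 adjusted over the list alone; median -1.55), among them the myelin basic protein Mbp, from 269 ± 129.6 to 92.0 ± 32.8 CPM. Smooth muscle genes fell in 7 of 9 members (7 adjusted over the list alone; median -1.10), among them the smooth muscle actin Acta2, from 179 ± 29.1 to 93.9 ± 7.43 CPM. Fibroblast and matrix genes fell in 8 of 18 members (13 adjusted over the list alone; median -0.69), among them the collagen Col1a1, from 3612 ± 915 to 1396 ± 490.2 CPM. Skeletal muscle genes fell in 3 of 20 members (0 adjusted over the list alone; median -1.31), namely the myosin Myh2, which overlaps 9430073C21Rik and is thus uncertain, the enolase Eno3 and the myosin light chain Myl1. These 3 calls lay near the threshold and were lost, with the same sign, with no filter (adjusted p = 0.119 for Myh2, 0.127 for Eno3 and 0.130 for Myl1), with each prefix alone, and without any 1 of the WT libraries, KI 1, KI 4 or KI 5 (adjusted p between 0.0514 and 0.112). The muscle level (mean log2 CPM) lay between 6.90 and 10.21 in KI and between 10.13 and 10.78 in WT libraries. Medians with EAS37 and EAS42 were -1.67 and -0.60 for adipocyte, -0.95 and -0.51 for endothelial and -1.86 and -1.65 for Schwann genes. They were -1.51 and -0.88 for smooth muscle, -1.14 and -0.34 for fibroblast and -2.25 and -1.06 for skeletal muscle genes.

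Camera called each of these 6 lists lower with the preset correlation, with adjusted p = 9.21e-06 for adipocyte, 1.22e-06 for endothelial, 1.56e-04 for Schwann, 2.74e-04 for smooth muscle, 2.11e-04 for fibroblast and 1.63e-05 for skeletal muscle genes. With an estimated correlation none was called, at adjusted p = 0.321 for adipocyte and smooth muscle, 0.352 for endothelial, 0.366 for Schwann, and 0.482 for fibroblast and skeletal muscle genes. With the muscle level in the model 3 of the 67 members of the 5 other lists passed, against 46 without it. With the adipocyte level in the model the fibroblast list turned and was called higher (camera adjusted p = 0.0189).

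**Figure D4:**
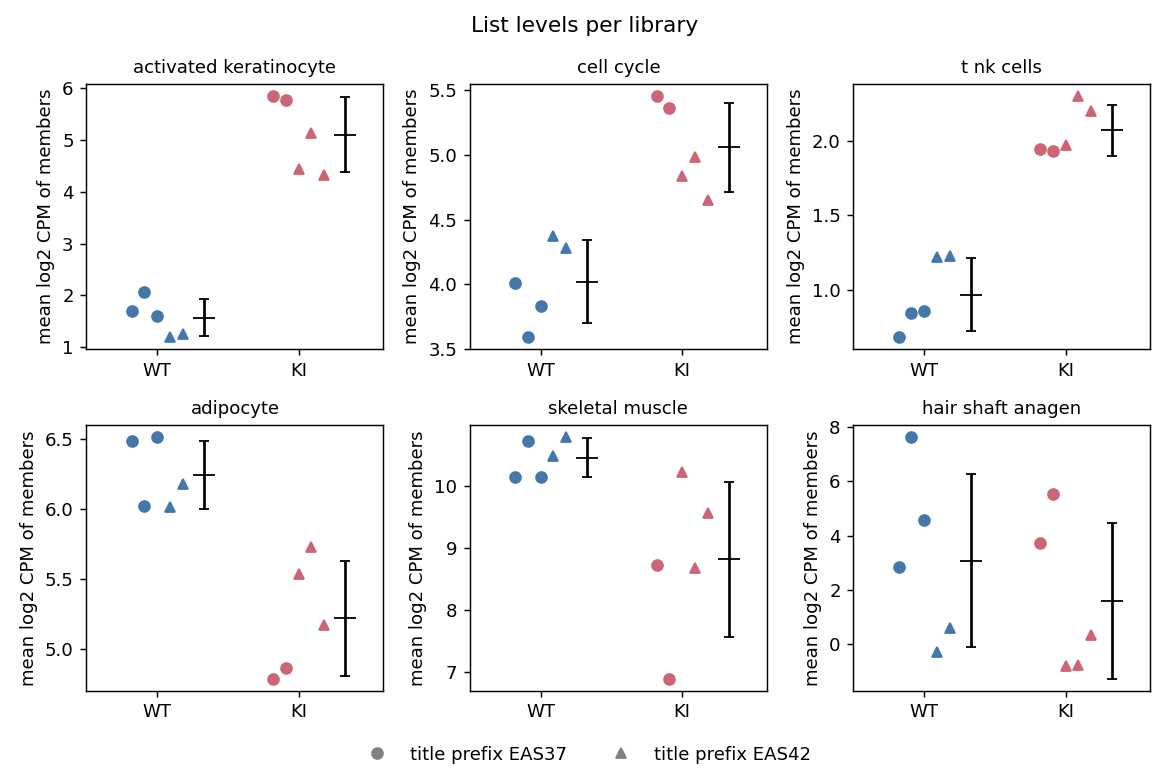
Mean log2 CPM over the measured members of 6 gene lists in each library, with circles for EAS37 and triangles for EAS42, and group mean with SD in black (n = 5). KI and WT libraries do not overlap for activated keratinocyte, cell cycle, T and NK cell and adipocyte genes, while hair keratin levels part by title prefix.

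Targets and inhibitors of BMP signalling, the pathway that controls hepcidin in the liver, fell in 9 of 13 members and none rose (10 adjusted over the list alone), with a median log2 fold change of -1.11. Within title prefixes the median was -1.08 with EAS37 and -0.39 with EAS42 (interaction camera adjusted p = 0.0144, and adjusted p = 0.620 with an estimated correlation). Id3, a BMP-induced inhibitor of transcription, went from 66.7 ± 5.73 to 29.0 ± 6.85 CPM, Smad9 from 4.52 ± 0.925 to 1.43 ± 0.558 CPM and the pseudoreceptor Bambi from 23.6 ± 7.58 to 7.39 ± 3.19 CPM (camera adjusted p = 3.19e-05, and adjusted p = 0.321 with an estimated correlation). In the same libraries the medians of adipocyte (-0.97), smooth muscle (-1.10), endothelial (-0.67) and Schwann (-1.55) markers were lower as well.

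Iron genes changed in part. Of 29 members 7 fell and 1 rose (7 and 1 adjusted over the list alone). The ferritin chains that store iron were lower, Fth1 from 827 ± 105 to 524 ± 94.3 CPM (log2 fold change -0.66 ± 0.14, edgeR adjusted p = 0.00625) and Ftl1 from 527 ± 62.2 to 409 ± 19.1 CPM (-0.36 ± 0.09, edgeR adjusted p = 0.0146). The ferroxidase Cp, the BMP ligand Bmp6 and the ferric reductase Cybrd1 fell as well, with log2 fold changes of -0.81 ± 0.17, -1.139 ± 0.25 and -1.78 ± 0.41 (SE). With EAS42 alone Ftl1 (adjusted p = 0.218) and Cybrd1 (0.130) did not pass, and with EAS37 alone Cp (0.0863) and Bmp6 (0.0615) did not. In the same libraries the medians of endothelial (-0.67), fibroblast (-0.69) and adipocyte (-0.97) markers were lower as well. The transferrin receptor Tfrc (80.3 ± 11.4 and 89.6 ± 26.02 CPM; edgeR adjusted p = 0.517) and ferroportin, Slc40a1 (69.8 ± 46.8 and 62.7 ± 24.6 CPM; edgeR adjusted p = 0.809), did not pass, and the list was not called (camera adjusted p = 0.198; fry called it lower, adjusted p = 0.00346, as did camera with the muscle level, adjusted p = 0.0265). Of 8 heme synthesis genes Alas1 and Cpox rose and Fech fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.906, upwards, against a median of -0.04).

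Other lists were not called by camera, each with its adjusted p and its members past the test, first over all genes and then adjusted over the list alone. Hair shaft genes had adjusted p = 0.0669 with 1 of 31 lower (1), the transcription factor Lef1, and sebaceous genes adjusted p = 0.0652 with 4 of 11 higher (4), among them the elongase Elovl3 (36.7 ± 6.37 to 229 ± 44.9 CPM). The hair list was called lower with no filter (0.0121), the muscle level (2.67e-08), the adipocyte level (4.23e-10), 1 surrogate variable (0.00958), EAS42 alone (0.0146), and without KI 1 (0.0109), KI 2 (0.00118), WT 4 (0.00498), WT 5 (0.0106) or WT 2 and KI 2 together (0.0212). The sebaceous list was called higher with no filter (0.0218), effective lengths (0.0421), the muscle level (0.00153), prefix and muscle level (0.00725), the adipocyte level (9.71e-05), EAS42 alone (0.00105), and without KI 1 (0.0300), WT 1 (0.0152), KI 2 (0.0148) or WT 2 and KI 2 together (0.0253). Hypoxia and glycolysis genes had adjusted p = 0.765 with 6 higher and 3 lower of 21 (6 and 3) and a median of -0.09 beside a mean of 0.15 and an upward camera direction, the glucose transporter Slc2a1 rising from 36.4 ± 4.85 to 162 ± 37.4 CPM. Interferon response genes had adjusted p = 0.198 with 2 higher and 1 lower of 27 (2 and 1). With the adipocyte level in the model the interferon (1.85e-08), mast cell (5.03e-05) and red blood cell (0.00384) lists were called as well. Immediate early genes had adjusted p = 0.695 with 4 higher and 2 lower of 15 (4 and 3), with a median of -0.07 and a mean of -0.21 beside an upward camera direction. Oxidative phosphorylation genes had adjusted p = 0.125 with 2 of 24 lower (0), and the list was called lower with EAS42 alone (0.0423), the adipocyte level (0.00600), and without KI 1 (0.0436) or KI 3 (0.0355). Melanocyte genes had adjusted p = 0.109 with 1 of 8 lower (1), Mitf, but the list was called lower with the title prefix as a block (0.00924), with each prefix alone (0.0316 and 0.0132), with no filter (0.0272), with the hair level (0.0114), with 1 surrogate variable (0.0226) and with prefix and muscle level (0.00704). Mast cell genes had adjusted p = 0.909 with 1 of 8 lower (1), Mrgprb2. B and plasma cell genes had adjusted p = 0.370 with 2 of 3 lower (2), Ighm and Mzb1, which lost their calls without KI 1 (0.0644 and 0.0733), WT 4 (0.0571 and 0.0738) or WT 5 (0.0568 and 0.0717), Ighm also without KI 2 (0.0671) or WT 3 (0.0727), and Mzb1 without KI 3 (0.0536) or KI 4 (0.0736). Red blood cell genes had adjusted p = 0.369 with 0 of 6 passing (0). Of the sex-linked list Xist alone was measured, at 803 ± 38.9 CPM in WT and 825 ± 37.3 CPM in KI (edgeR adjusted p = 0.724).

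The effect of the KI genotype was compared between the title prefixes by an interaction test. It differed for 150 genes (edgeR adjusted p under 0.05), and cell cycle genes stood out with 11 of 35 members passing. Their median log2 fold change was 1.75 with EAS37 and 0.56 with EAS42, and Cenpa, for example, had log2 fold changes of 1.75 with EAS37 and 0.92 with EAS42 (interaction adjusted p = 0.0467). The cell cycle level of WT libraries (mean log2 CPM) was itself lower with EAS37, at 3.81 against 4.33 with EAS42. Camera on the interaction placed the cell cycle list apart from other genes (adjusted p = 7.04e-27, and adjusted p = 0.620 with an estimated correlation). The count of 150 ranged with 1 library left out from 1 (KI 1 or WT 4), 2 (KI 2), 10 (WT 5), 12 (KI 3), 37 (WT 1) and 79 (KI 5) to 304 (WT 2).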

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

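Tests of chance over splits of the libraries, and of a larger effect of every gene with prefix EAS37, were set before their results were seen, and the other tests in this part were chosen after. Of the 126 possible splits of the 10 libraries into 5 and 5, 100 were run. Of these, 1 (the genotypes, 5351 genes) reached that number, and the highest other was 50 genes, from the split that follows the title prefixes. A share of 1 in 100 splits, the smallest that this number of splits allows, argues against chance for this count but does not exclude it. Every other split mixed the genotypes, so a genotype difference adds spread within its sides and lowers its count.

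Adipocyte, endothelial, Schwann, smooth muscle, fibroblast matrix and skeletal muscle lists were called lower in KI skin with the preset correlation, none of them with an estimated one, and only 8 of 18 matrix and 3 of 20 skeletal muscle genes passed. With the muscle level in the model the median log2 fold change of the 67 members of the 5 lists other than skeletal muscle went from -0.92 to -0.65, their median standard error from 0.234 to 0.289, and members passing from 46 to 3. The calls ended through both a smaller change and a larger error, as genotype holds 50.4% of the variance of the muscle level. For muscle as the cause a bound of -0.2 was set for the median, and the median of -0.65 lay below it. Since list members are correlated, the bound was also applied, after the first results, to their mean level over libraries. That level differed by -0.66 (95% interval -1.14 to -0.18), an interval that reaches just past the bound. A larger share of epidermal RNA would lower the 6 lists alike and raise basal keratinocyte genes. The basal level hardly moved (-0.04, 95% interval -0.17 to 0.08), so the rise that such dilution predicts was not seen, and T and NK cell genes rose. Both results argue against dilution as the whole cause, but not against a part in it. Whether the lists fell alike was not settled. A permutation test over genes, which treats correlated genes as independent, gave p = 1e-04, the smallest its permutations allow. An exact permutation test over libraries, taken up after the first results, did not separate the list falls (exact permutation p = 0.143 for 6 lists, 0.0635 for 5). This does not show them equal. Less muscle and a loss of these tissues with the genotype cannot be told apart, since the interval with the muscle level reaches past its bound.

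Hamp2 fell where Hamp rose. Of the 50-base windows of Hamp2 transcripts 11.2% also occur in Hamp transcripts. This lies between the bounds of 10% and 50% first set, which left the test undecided. A comparison added once the share was seen set it against the fall of Hamp2, 93.3% (71.3% at 2 standard errors, without the muscle level in the model). That fall exceeds the share of exactly matching windows, which argues against a transfer of such reads as the whole cause. Matches with mismatches were not counted. Expected counts of both genes had a fractional part of at most 0.11. Loss of deep tissue stays open, since the Hamp2 change plus 2 standard errors (-1.80) lies below the lower quartile of the 6 lists (-1.35) but with the muscle level in the model the change was -2.51 ± 1.49 (SE). A haplotype around the Hamp genes that differs between genotypes cannot be told apart from an effect of hepcidin: 7 of 40 neighbours within 500 kb were called (17.5%, against 30.9% of all genes; Fisher exact p = 0.0852), not the excess that a wide haplotype effect would give, but a change in Hamp2 alone would leave neighbours as they are.

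Cell cycle genes rose more with prefix EAS37 (interaction adjusted p = 7.04e-27 by camera with the preset correlation, 0.620 with an estimated correlation). Part of this lies in WT skin, where the cell cycle level was 3.81 with EAS37 (at most 4.01) and 4.33 with EAS42 (at least 4.28). The WT difference, EAS37 minus EAS42, was -0.51 (95% interval -1.03 to -0.0012). The difference of the KI effects, taken the other way (EAS42 minus EAS37), was -1.10, so the KI effect was larger with EAS37. A growth phase of hair in EAS37 mice cannot be told apart from the prefix as a source of a larger KI effect, because hair levels did not overlap between prefixes (2.85 or more with EAS37, 0.60 or less with EAS42), although the difference of the KI effects on the cell cycle level, EAS42 minus EAS37, was -1.12 with the hair level in the model (95% interval -1.38 to -0.86). Larger effects of every gene with EAS37 would give one ratio, but called genes outside the list had a ratio of 1.52 and the list 3.15. The list level exceeded the scaled change by 0.85 (95% interval 0.20 to 1.49, with the ratio of 1.52 taken as fixed). Cell cycle had the lowest interaction adjusted p of all lists, so this excess may be overstated by selection. It was not the only such list. Cornified and adipocyte medians were also much larger with EAS37, while activated keratinocyte and Schwann medians were similar with both prefixes. Litter, age or breeding line, which the prefix may stand for, stay open and untested.

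The KI effect differed between title prefixes for 150 genes in all, a number that fell to 1 without KI 1 or WT 4. Among named genes these were Cenpa (interaction adjusted p = 0.0467), Trbc2 (0.0488; log2 fold change 1.83 with EAS37 and 0.72 with EAS42) and Pnpla2 (0.0341; -1.23 and -0.29). By camera with the preset correlation the lists that differed, besides cell cycle, were cornified differentiation (adjusted p = 4.13e-16), sebaceous gland (1.31e-04), fibroblast matrix (2.25e-04), adipocyte and skeletal muscle (8.19e-04 each), activated keratinocyte (0.00123), BMP targets (0.0144), T and NK cells (0.0318) and immediate early genes (0.0365). With an estimated correlation no list differed, the lowest adjusted p being 0.620.

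A library stood apart from the other 4 of its group in 20 of 324 comparisons, where chance gives about 16.2. In KI 5 these were Lce1g (43.6 CPM), Casp14 (330 CPM), Flg (346 CPM), Egr2 (116 CPM), all lower, and Mrgprb2 (9.27 CPM), higher. In WT 3 they were Cp (38.8 CPM), Mx1 (1.67 CPM) and Olah (0.0778 CPM), higher, and Car9 (0.506 CPM), lower. In WT 4 they were Cd207 (12.5 CPM), higher, and Alas1 (42.5 CPM) and Cd5 (0.72 CPM), lower. In WT 2 they were Oas1a (0.318 CPM) and the levels of the neutrophil and interleukin 17 axis (-0.76) and interferon lists (1.53), all lower. Single cases were Alas1 in KI 1 (80.1 CPM), Hdc in KI 4 (10.5 CPM) and the heme synthesis level in WT 1 (5.34), higher, and Acta2 in KI 2 (80.7 CPM) and Tnfrsf13c in KI 3 (0 CPM), lower. Olah had 2 counts over all WT libraries and Tnfrsf13c 17 over all KI libraries, so their cases lie near the floor.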

How the results depend on the processing

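Leaving out WT 2 and KI 2 together, the prefix block with the muscle level, and the adipocyte covariate were chosen after seeing the data. No paired analysis was possible because replicate numbers were given in accession order and the labels pair no mice. The count of changed genes lay between 3821 (without KI 1) and 5850 (without KI 5) when 1 library was left out, with 1936 to 3038 higher and 1799 to 2812 lower, and between 4472 and 6650 under the other normalizations, filters, tools and covariates named in the methods, except for the following. It was 2488 with EAS42 alone (1192 higher, 1296 lower), 414 with the muscle level as covariate (283 and 131), 722 with the title prefix and the muscle level (397 and 325) and 109 with the adipocyte level (90 and 19), of which 413, 655 and 104 were among the 5351. Without WT 2 and KI 2 it was 3685, with 1789 higher. Muscle and adipocyte levels themselves differ by genotype, so these covariates remove part of the genotype effect by construction. For EAS42 alone the cause was not tested, as EAS37 alone has as many libraries and called 5064. The Hamp log2 fold change stayed between 5.09 and 5.64 and was called under every alternative run. Lists called higher numbered 7 to 11 and lists called lower 7 to 10, except that camera with an estimated correlation called 0 and 0 (4 lists at an unadjusted p under 0.05), while fry called 8 and 8. The interaction count was 164 with a stricter filter, 1087 with DESeq2 and 1 to 304 with 1 library left out (37 without WT 1, 2 without KI 2, 12 without KI 3, 10 without WT 5 and 79 without KI 5); the cause was not tested. Over named genes, 3195 of 3571 gene and setting pairs kept direction and side of the threshold, 333 lost the call, 41 gained it and 2 turned, namely Myh2 with the title prefix and muscle level (0.0198, adjusted p = 0.985) and Ighm with the adipocyte level (0.225, adjusted p = 0.876). Most lost calls came from 3 settings. Of the 134 named genes, 90 lost the call with the adipocyte level, 65 with the muscle level and 60 with prefix and muscle level. Over lists, 666 of 726 kept theirs, 21 lost it, 36 gained it and 3 turned, namely skeletal muscle with the muscle level (adjusted p = 0.747) and with prefix and muscle level (0.966), by construction, and fibroblast matrix with the adipocyte level (0.0189), where the cause was not tested. Depth limits genes with few counts, such as Olah with 2 WT counts.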

Other observations

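Further genes of 2 groups rose in KI skin, and the genes in this part were chosen after their values were seen. Beside BC100530 and Stfa3, other genes of the stefin cluster on chromosome 16 were higher, Stfa1 from 1.12 to 47.2 CPM (log2 fold change 5.40 ± 0.44, edgeR adjusted p = 1.03e-04) and Stfa2 from 0.107 to 5.04 CPM (5.51 ± 0.52, edgeR adjusted p = 1.32e-04). BC117090 had 0 counts in WT and 181 in KI, at least 65.0-fold higher against a floor of 3 counts over the WT group. These copies are similar and their split of reads is uncertain. The collagenase Mmp13 went from 0.346 to 24.5 CPM (6.12 ± 0.63, edgeR adjusted p = 3.48e-04) and the gasdermin Gsdmc from 0.386 to 28.4 CPM (6.15 ± 0.57, edgeR adjusted p = 1.98e-04).

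Sterol synthesis genes may have risen as a set, a hypothesis from seeing some of them among the top genes. Of 22 genes on a list written afterwards 17 rose and 0 fell, with a median log2 fold change of 0.70. Camera with the preset correlation gave p = 4.64e-10 (p = 3.23e-08 for the 20 genes that had not prompted the list), but p = 0.0792 with an estimated correlation (p = 0.0997 for the 20 genes). With EAS37 the sterol median was 0.80 and the sebaceous median -0.19. The difference of list levels there was 0.94 (95% interval 0.47 to 1.41, 2 against 3 libraries). With EAS42 the medians were 0.64 and 0.86. The 4 sebaceous genes called higher also rose with EAS37 (log2 fold changes 2.42 for Elovl3, 1.20 for Dgat2l6, 0.75 for Awat1 and 0.49 for Far2). The sebaceous list thus moved both ways with EAS37, and a rise of sebaceous gland content stays open.

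Gt(ROSA)26Sor, a transcript of a locus widely used as an insertion site in mice, was at 10.4 CPM in WT 1 and 11.6 CPM in WT 3, and between 0.571 and 1.143 CPM in the other 8 libraries, KI and WT. Its call as lower in KI (log2 fold change -2.54 ± 0.87, edgeR adjusted p = 0.0481) thus rests on 2 WT libraries. It overlaps Thumpd3 on the other strand, and the labels name no insertion site.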
